A study of Mus musculus with 8 samples.

How the data were processed

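RNA was sequenced from 8 mouse libraries. The labels describe airway cells taken 10 days after tamoxifen from animals with a Cre recombinase driven by Scgb1a1, the gene of the main secreted protein of club cells. Club cells are secretory cells of the small airways. The 4 control libraries carried the Cre and 1 floxed allele of Cdh1, which encodes the adhesion protein E-cadherin. The 4 libraries labelled mutant carried 2 floxed alleles. The series text describes removal of immune and endothelial cells, selection for EPCAM and a sort on GFP, but no label says which sorted fraction a library holds. The labels name both a stranded and an unstranded library kit from Illumina, so the kit of each library is not known. The description of each library ends in a different number, and nothing states in words that the libraries came from separate animals, so p-values measure the spread between these libraries.

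The deposited table holds raw fragment counts per gene, 1 column per library. Per the file headers, the authors counted read pairs with featureCounts 1.6.2 against the GENCODE release M25 annotation of GRCm38. Per the file headers, strand was not used, reads mapping to several places were not counted, and reads over more than 1 gene were not counted. Reads of a gene and of an antisense partner therefore cannot be told apart, and near-identical paralogs lose the reads they share. The submitters' processing notes also name STAR, Bowtie2 and Cufflinks without roles. No pooling of libraries is recorded, and the 8 columns were all used.

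Symbols and GC content came from GENCODE release M21 on the same build, which matched 99.53% of the 55401 gene identifiers. Coordinates are those of the deposited table. Total counts per library ran from 15111663 to 21673654, so that 3 counts, the upper limit that a count of 0 allows, correspond to 0.138 to 0.199 CPM, the count scaled to a common library total. This floor covers counting error only. Chi-square per gene between libraries of a group ran from 4.88 to 45.58, so no pair agreed within sampling noise and each library was counted once. All 8 libraries had at least 4773 counts of Xist, and 41 counts of Y-linked genes occurred in control 1 with 0 in the others.

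Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 16964, and scaled with TMM. The groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, robust fit, group as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic. CPM values use the TMM-scaled library sizes.

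Before the data were examined, 37 gene lists were written for airway, alveolar, immune, stromal and endothelial cell types and for adhesion, stress, immune and repair programmes. The 36 lists with at least 3 measured members were tested with camera from limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. The remaining list, of sex-linked genes, had only Xist measured. The mean log2 CPM of each list per library was compared by an exact two-sided permutation test over 70 arrangements, whose smallest possible p is 0.0286.

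Genes named in the text followed a rule fixed at the same time: Cdh1, then the 12 largest increases and the 12 largest decreases among genes that passed the threshold, had an average log2 CPM of at least 1 and did not overlap between groups, up to 4 members of each list with the lowest adjusted p, and members needed to say what a count is made of. Members named under the last part were picked after their values were seen. Epcam, Sftpc, Fgfr2, Mki67, Cdc20b, Ptprc and the genes of lists written later fall outside it and were chosen after their values or those of their group were seen. Predicted genes, pseudogenes, immunoglobulin and T cell receptor segments and genes known only by a clone name were left out of the largest changes. That removed 40 candidates among the increases and 17 among the decreases, of which 1 would have ranked among the 12. A pair of genes that the rule names, 1 of them among the 12 largest decreases, is not reported here, and no other gene took their place.

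The test was tried on simulated data with 200 changed genes among the 16736 genes that passed the filter. It recovered 53.7% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 98.5% of those changed 4-fold, and 3.8% of its calls fell on unchanged genes. The simulated genes varied independently and equally in both groups. These shares therefore leave out genes that move together and the wider spread of the real controls. Changed genes were drawn only from those with a positive average log2 CPM, so the shares recovered leave out the least expressed genes. A simulated GC trend gave a rank correlation of 0.649 between fold change and GC content, and -0.002 after correction.

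Alternatives covered other scaling, other filters, DESeq2 1.42.0, limma-voom with and without quality weights, a fit without robust estimation, the replicate number as a block, a surrogate variable from sva 3.50.0, stricter thresholds, each library left out in turn, and control 1 and mutant 4 left out together because their descriptions hold adjacent numbers across the groups. Mutant-labelled libraries 1 and 2 also hold adjacent numbers and library 3 a near one, while those of the 4 controls lie far apart. A covariate for sex could not be fitted, since no library looked male. Alternatives without controls 2 and 3, without controls 1 and 4 and with the GC trend of each library removed were chosen after the data were seen.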

Results

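Gene expression was measured in 8 libraries described as airway cells taken 10 days after tamoxifen, 4 labelled control and 4 labelled mutant for Cdh1 in club cells. The question posed by the series was which genes change in airway cells once E-cadherin is removed from club cells. Total counts were 20454930, 15111663, 17986668 and 19684410 in controls 1 to 4 and 16981201, 18143332, 17414504 and 21673654 in the mutant-labelled libraries 1 to 4. The groups are called control and mutant-labelled because the level of Cdh1 offered no check of the labels. Sftpc, the surfactant protein of alveolar type II cells, was the most abundant gene in 7 of the 8 libraries, and Scgb1a1 was the most abundant in control 1. Mitochondrial genes took 1.25% to 1.88% of the counts.

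In mutant-labelled libraries 20 of 40 club cell genes fell and 6 rose, and 8 of 13 goblet cell genes, 14 of 31 genes of damaged epithelium and 23 of 51 ciliated cell genes rose. Camera called these 4 lists, and the calls of the club, goblet and ciliated lists were lost with an estimated correlation (adjusted p = 0.308, 0.137 and 0.308 with an estimated correlation). Scgb1a1 fell 3.21-fold from 13400 ± 554 to 4177 ± 307 CPM (SD, n = 4 each), Dmbt1, a secreted mucosal defence protein, rose 122-fold from 0.248 CPM, near the floor, Clu, a secreted chaperone, rose 10.3-fold, and Ccno, needed for centriole amplification, rose 8.96-fold. Of 16964 genes tested, 924 were higher and 401 lower at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At a change of 2-fold or more the numbers were 406 and 96. Groups did not overlap for 1284 of the 1325 called genes, and for 16.8% of all tested genes, where chance gives 2.86%. The controls spread widely: on the first principal component, 48.8% of the variance, controls 1 to 4 lay at -4.1, -46.5, -53.7 and -9.8, and the mutant-labelled libraries between 24.5 and 31.6. Without controls 2 and 3 the fit called 628 genes higher and 223 lower, and without controls 1 and 4 it called 3750 and 3338. Leaving out 1 library moved the count of lower genes by over 1.5 times in each case: 1117, 189, 207 and 749 without controls 1 to 4, and 146, 186, 182 and 217 without mutant-labelled libraries 1 to 4. For higher genes this held without control 1 (1517) and without mutant-labelled libraries 1, 2 and 4 (515, 534 and 576). Of 107 named genes that were called, 0, 31, 26 and 8 lost the call without controls 1 to 4, and 34, 30, 28 and 26 without mutant-labelled libraries 1 to 4. Removing the GC trend of each library left 565 higher and 124 lower, which moved the share of higher genes from 69.7% to 82.0%.

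**Figure D1:**
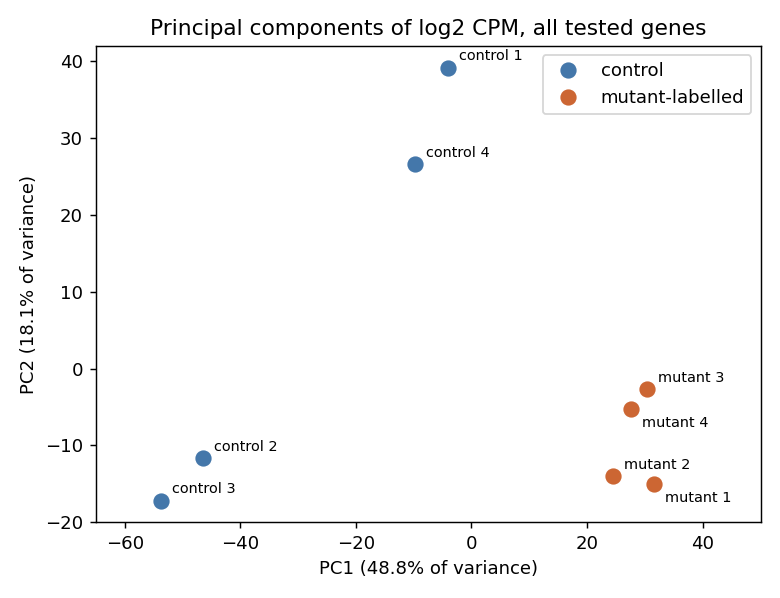
Each point is a library on PC1 (48.8% of the variance) and PC2 (18.1%) of log2 CPM over the tested genes. The 4 mutant-labelled libraries lie between 24.5 and 31.6 on PC1, and the controls between -53.7 and -4.1.

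The targeted gene did not separate the groups. Cdh1 (ENSMUSG00000000303, GRCm38 chromosome 8, 106603351 to 106670246) stood at 383.5 ± 44.7 CPM in controls and 403.4 ± 6.08 CPM in mutant-labelled libraries (SD, n = 4 each). The log2 fold change was 0.07 ± 0.09 (SE), with an adjusted p of 0.648 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and a 95% interval of the ratio from 0.902 to 1.23. A sum over the whole gene cannot show the loss of floxed exons, and the controls already carried 1 floxed allele. Every direction reported therefore rests on the labels. Markers of other lung cells were abundant in both groups: the endothelial gene Pecam1 stood at 1173 ± 183 CPM in controls, against 67.1 ± 6.91 CPM for the epithelial gene Epcam. The libraries therefore held RNA of a mix of lung cells, although the series text describes removal of endothelial cells. A change, or the absence of a change in Cdh1, may reflect the share of a cell type, which was not measured. In mutant-labelled libraries Epcam was 1.53-fold higher and Pecam1 1.39-fold lower. Their adjusted p was 0.00299 and 0.0369 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The 95% interval of the Epcam ratio, from 1.32 to 1.78, lay above that of Cdh1.

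**Figure D2:**
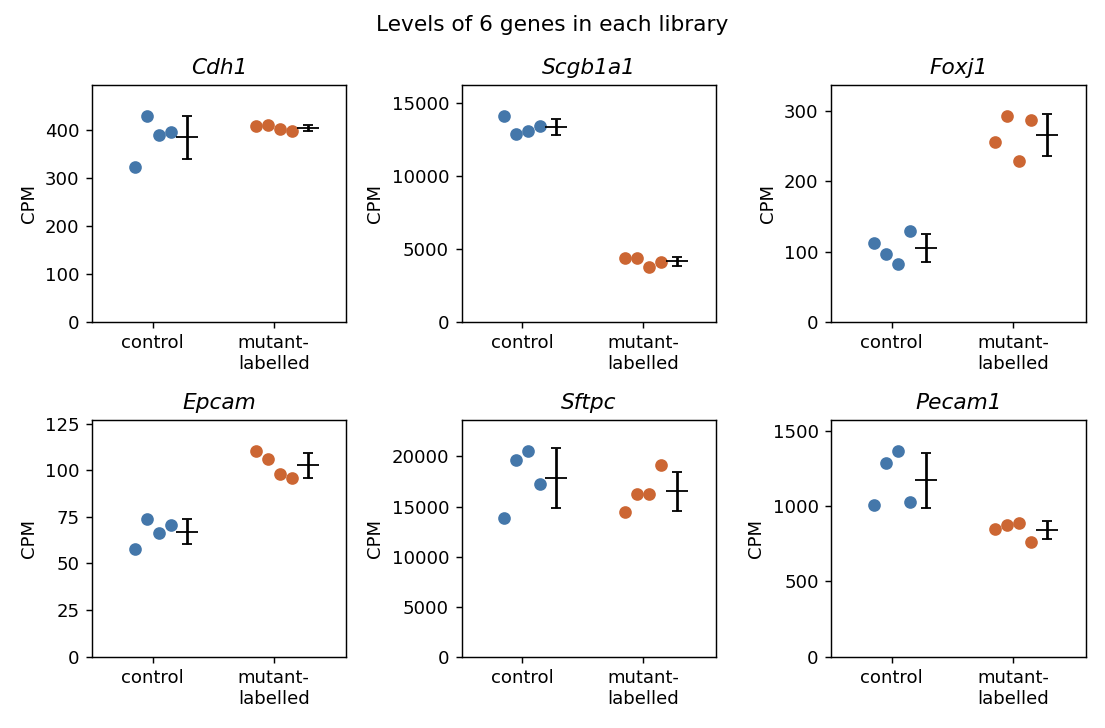
CPM of Cdh1, Scgb1a1, Foxj1, Epcam, Sftpc and Pecam1 in each library, with each group's mean and SD beside the points (n = 4). Scgb1a1 fell from a mean of 13400 to 4177 CPM without overlap, Foxj1 and Epcam were higher in every mutant-labelled library, and Cdh1 and Sftpc overlapped.

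The 12 largest increases by the rule for named genes began with Dmbt1, from 0.248 ± 0.10 to 31.3 ± 11.1 CPM (SD, n = 4 each). The others ran from 46.7-fold to 11.3-fold: the serine protease gene Prss22, Sectm1b, the prodynorphin gene Pdyn, Sectm1a, Fgl1, the cornified envelope gene Sprr1a, the claudin genes Cldn2 and Cldn4, the cyclin gene Ccna1, Cdhr1 and Mcidas, a master regulator of multiciliated cells. Control means of Prss22, Pdyn, Fgl1, Sectm1a, Dmbt1 and Sectm1b ran from 0.166 to 0.279 CPM, near the floor of 0.138 to 0.199 CPM. The size and order of these folds are therefore uncertain. Cldn4 rose from 6.53 ± 1.88 to 82.8 ± 10.9 CPM. The decreases named here, 11 of the 12 largest, were Pon1, at 73.7 ± 8.61 CPM in controls and 7.52 ± 0.641 CPM in mutant-labelled libraries, and Azgp1, Gsta2, Ces1f, Scgb1c1, Atp2b2, Cyp2f2, Ankrd63, Scgb1a1, Cyp2a5 and Slc10a5, which fell between 8.93-fold and 3.11-fold. Adjusted p for these 23 genes ran from 9.98e-07 to 0.0106 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. When 1 library was left out, 0 of the 23 lost the call. They were picked over all libraries as called, without overlap and most changed, which favours that outcome. Sectm1a and Sectm1b, and Ces1f, Cyp2a5 and Gsta2 with their paralogs, share sequence, so their levels are uncertain. The span of Dmbt1 (chromosome 7, 131032046 to 131121628) lies inside that given for Fgfr2, whose log2 fold change was -0.13 ± 0.11.

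**Figure D3:**
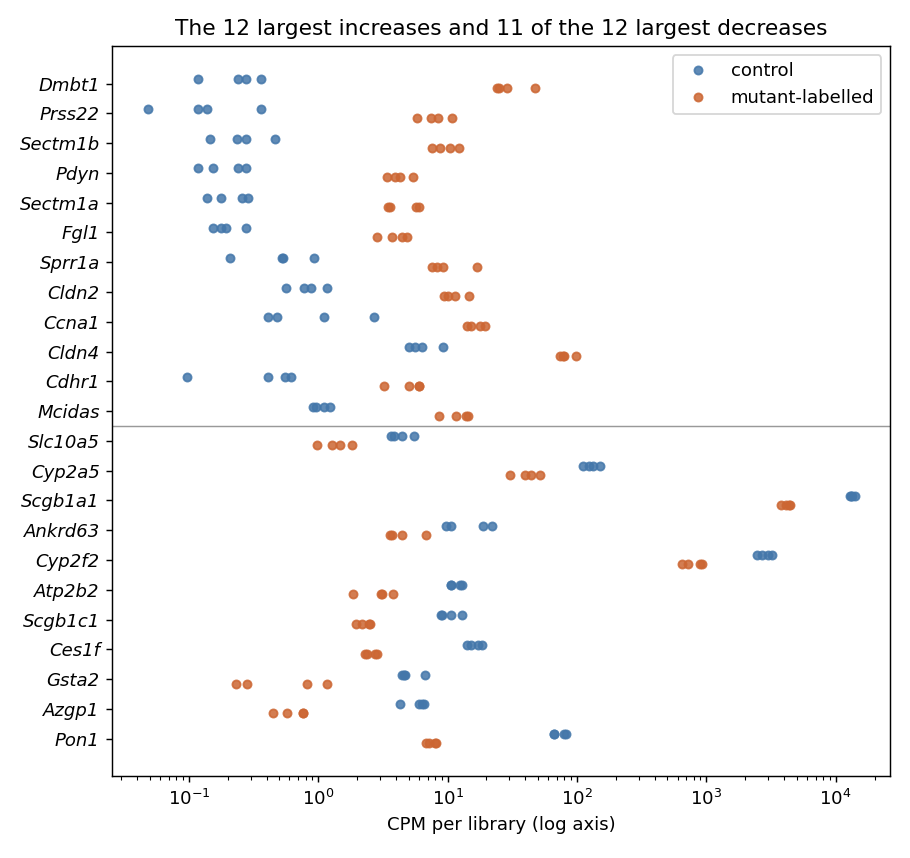
CPM on a log axis in each library for the 12 largest increases (above the line) and 11 of the 12 largest decreases (below the line). The rule that picked these genes required no overlap between the 4 control and the 4 mutant-labelled libraries. Scgb1a1 is the most abundant of the 23.

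Of 40 measured club and secretory cell markers, 20 fell and 6 rose, or 24 and 7 adjusted over the list alone. Next to Scgb1a1 and Pon1, the xenobiotic enzyme gene Cyp2f2 fell 3.55-fold from 2840 ± 328 CPM, Cbr2 2.85-fold and Aldh1a1 1.99-fold. The 6 that rose were Retnla (9.55-fold), Reg3g (5.44-fold), Muc5b (4.25-fold), Bpifb1 (3.15-fold), Nupr1 (2.52-fold) and Scgb3a1 (1.81-fold), which are known as secreted defence, mucus or stress genes. Epcam rose 1.53-fold and Pecam1 fell 1.39-fold in the same libraries. By camera the list was lower with an adjusted p of 2.4e-12, and an adjusted p of 0.308 with an estimated correlation. A separate list of detoxification and redox genes gave 12 lower and 4 higher of 40, or 16 and 6 adjusted over the list alone. Among them catalase (Cat) fell 1.61-fold and Aldh3a1 2.01-fold, while Akr1b8 rose 2.37-fold, Gsto1 1.85-fold, the glutathione synthesis gene Gclc 2.16-fold and Gpx2 also rose. Camera gave this list an adjusted p of 0.005, and an adjusted p of 0.528 with an estimated correlation and of 0.0502 without mutant-labelled library 3. Without mutant-labelled library 1, 7 members fell, and without control 1, 7 rose.

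Goblet cell genes rose in 8 of 13 measured markers and fell in 0, or 9 and 0 adjusted over the list alone. Besides Dmbt1 and Muc5b these included the mucin gene Muc5ac, from 6.21 ± 1.40 to 30.6 ± 6.04 CPM, Agr2, a mucin-folding protein (7.94-fold), Gp2 (9.70-fold) and the transcription factor genes Foxa3 (3.67-fold) and Spdef (1.68-fold). Epcam was 1.53-fold higher and Pecam1 1.39-fold lower in these libraries. By camera the goblet list had an adjusted p of 2.64e-16, and an adjusted p of 0.137 with an estimated correlation. Inflammation genes rose in 9 of 36 and fell in 0, or 11 and 1 adjusted over the list alone. The antimicrobial genes Ltf (7.13-fold), Reg3g and Lcn2 (2.64-fold), the alarmin Il33 (3.32-fold), Cxcl17 (2.70-fold), Ccl20 (3.10-fold), Cxcl5, Il6 and Ptgs2 made up the 9. Camera gave an adjusted p of 3.46e-11, and an adjusted p of 0.308 with an estimated correlation. Without control 1, 22 members rose, and without controls 2 and 3, 6 rose and the median log2 fold change was 0.095, against 0.397 with all libraries. The list mean of control 1, 4.46 log2 CPM, lay close to the 4.52 to 4.92 of the mutant-labelled libraries, in which the myeloid genes Chil3 (2.01-fold), Mrc1 (1.72-fold), Cd14 (2.10-fold) and Cd68 (1.51-fold) also rose. Interferon genes rose in 3 of 42, namely Oasl1 (2.56-fold), Oas2 (1.89-fold) and Usp18 (1.29-fold), or 5 with 1 lower adjusted over the list alone. Camera gave an adjusted p of 0.0469, and an adjusted p of 0.837 with an estimated correlation. The interferon call was lost without control 2 (0.196), control 3 (0.123), control 4 (0.251) or mutant-labelled library 3 (0.449), without controls 2 and 3 together (0.729), with scaling by library size (0.0747) and with a surrogate variable (0.237). Without control 1, 17 interferon genes rose and camera gave an adjusted p of 8.95e-07.

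Genes of damaged and transitional epithelium rose in 14 of 31 and fell in 0, or 18 and 0 adjusted over the list alone. Clu rose from 300.2 ± 54.2 to 3100 ± 247 CPM and Areg, an EGF receptor ligand, from 4.51 ± 0.329 to 36.8 ± 6.06 CPM. Sfn (3.42-fold), the keratin genes Krt8 (2.02-fold), Krt18 (2.09-fold) and Krt19 (2.14-fold), Anxa1 (2.06-fold) and Itgb6 (2.09-fold) rose with them. The epithelial marker Epcam rose 1.53-fold and Pecam1 fell 1.39-fold in the same libraries. Of the 36 lists fixed before the data were examined, this one alone passed camera both at the preset correlation, with an adjusted p of 4.25e-29, and with an adjusted p of 0.00757 with an estimated correlation. Tight junction genes rose in 6 and fell in 1 of 27, or 7 and 2 adjusted over the list alone. Next to Cldn4, Cldn2 (13.6-fold) and Cldn6 (18.3-fold), Cldn7 rose 1.79-fold and Tjp3 1.87-fold, and Cldn23 also rose, while Cldn10 fell 1.90-fold. Cldn6 stood at 0.155 CPM in controls, near the floor, so the size of its fold is uncertain. The list's median log2 fold change was 0.03 and its mean 0.44, and camera gave an adjusted p of 0.00107, and an adjusted p of 0.528 with an estimated correlation. Tight junction genes gave 7 higher and 5 lower without control 1, 6 and 2 without control 4, and 7 and 8 without controls 1 and 4. Camera's adjusted p for this list was 0.612 without controls 1 and 4 and 0.0677 without control 1 and mutant-labelled library 4. Of 26 cadherin, catenin and nectin genes, Nectin2 rose 1.43-fold and Cdh13 fell 1.40-fold, also when adjusted over the list alone, and camera gave an adjusted p of 0.931. This list gave 2 higher and 3 lower without control 1 and 5 higher and 1 lower without control 4, and 0 lower without control 2 or 3 or mutant-labelled library 1, 2 or 4.

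Ciliated cell genes rose in 23 of 51 and fell in 1, Sec14l3, or 34 and 1 adjusted over the list alone. The largest increases in this list were those of Mcidas (11.3-fold), Foxn4 (10.96-fold), Ccno (8.96-fold) and Deup1 (6.67-fold), which act in the formation of multiciliated cells. The ciliary transcription factor gene Foxj1 rose 2.53-fold, from 105 ± 20.3 to 266.2 ± 30 CPM, and Myb 1.92-fold, next to the axonemal genes Lrrc23 (2.60-fold), Dynlrb2 (2.19-fold) and Cfap53 (2.02-fold). Epcam rose 1.53-fold and endothelial genes fell in the same libraries. By camera the adjusted p was 4.47e-26, and an adjusted p of 0.308 with an estimated correlation. Without controls 2 and 3, 19 rose and 1 fell.

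Proliferation genes rose in 13 of 49 and fell in 0, or 37 and 0 adjusted over the list alone. Ect2 (2.73-fold), Cdc20 (2.77-fold), Plk1 (2.99-fold), Aurka (2.45-fold) and Cdk1 (2.72-fold) were among them, and Mki67, at 42.3 ± 36.8 CPM in controls and 93.5 ± 27.6 CPM in mutant-labelled libraries, was not called. In the same libraries Epcam was 1.53-fold higher and Pecam1 1.39-fold lower. By camera the adjusted p of this list was 1.81e-17, and an adjusted p of 0.528 with an estimated correlation. The list mean was 4.19, 3.15, 2.88 and 3.52 log2 CPM in controls 1 to 4 and 4.54, 4.32, 4.73 and 4.16 in mutant-labelled libraries 1 to 4, so the groups overlapped. The number of members that rose was 4 without controls 2 and 3, 42, 6 and 7 without control 1, 2 or 3, and 5, 5, 5 and 8 without mutant-labelled library 1, 2, 3 or 4.

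Some markers of alveolar, endothelial and myeloid cells were also called, and 0 of 21 lymphoid markers were. Alveolar type II genes rose in 5 of 24, or 8 adjusted over the list alone, with Il33, Egfl6 (1.83-fold), Sftpd (1.54-fold), Cxcl15 (1.47-fold) and Scd1 (2.0-fold) as the 5, and Sftpc at 17860 ± 2990 and 16520 ± 1950 CPM. Alveolar type I genes fell in 2 of 20, Sec14l3 (1.55-fold) and Rtkn2 (1.29-fold), or 4 adjusted over the list alone. Camera gave adjusted p of 3.13e-05 and 0.00656 for these lists, and an adjusted p of 0.528 for each with an estimated correlation. Alveolar type I genes gave 8 lower without control 1, 4 lower and 2 higher without control 4, and 1 lower without mutant-labelled library 1 or 2. The number of alveolar type II genes that rose was 3 without control 2 or mutant-labelled library 2 or 3 and 8 without control 4, and camera gave the list an adjusted p of 0.061 without control 1 and mutant-labelled library 4. Endothelial genes fell in 6 of 20, or 15 adjusted over the list alone, among them Tek (1.57-fold), Ramp2 (1.52-fold), Cdh5 (1.31-fold) and Pecam1. Camera gave the endothelial list an adjusted p of 1.01e-06, and an adjusted p of 0.308 with an estimated correlation. The number of endothelial members that fell was 1 without controls 2 and 3, 11, 0 and 1 without control 1, 2 or 3, and 0, 0, 1 and 0 without mutant-labelled library 1, 2, 3 or 4. Notch genes fell in 4 of 19, namely Dll4 (1.54-fold), Hey1 (1.48-fold), Mfng (1.39-fold) and Lfng (1.22-fold), or 7 with 1 higher adjusted over the list alone. Dll4 and Hey1 are also expressed by endothelial cells. Camera gave the Notch list an adjusted p of 0.0216, and an adjusted p of 0.308 with an estimated correlation. That call was lost without control 1 (0.0664), control 4 (0.0698) or mutant-labelled library 4 (0.0561), without controls 1 and 4 together (0.482) and without control 1 and mutant-labelled library 4 together (0.153), and 2 members fell without control 2 or 3 or mutant-labelled library 1, 3 or 4.

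Myeloid genes rose in 6 of 26, both over all genes and adjusted over the list alone, including the macrophage genes Chil3 (2.01-fold), Mrc1 (1.72-fold), Cd14 (2.10-fold) and Cd68 (1.51-fold). Camera gave an adjusted p of 0.00182, and an adjusted p of 0.606 with an estimated correlation. Without controls 2 and 3 the adjusted p was 0.454 and the median log2 fold change -0.17. The number of myeloid members that rose was 10 without control 1 and 3 without control 2 or mutant-labelled library 1 or 4. Of 51 ribosomal protein genes Rpl30 fell 1.32-fold, with 0 called adjusted over the list alone. Camera called that list lower with an adjusted p of 0.00238, and an adjusted p of 0.723 with an estimated correlation. The number of ribosomal protein genes that fell was 8 without control 1, 28 without controls 1 and 4, and 0 without control 2 or 3 or mutant-labelled library 1, 2 or 3.

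**Figure D4:**
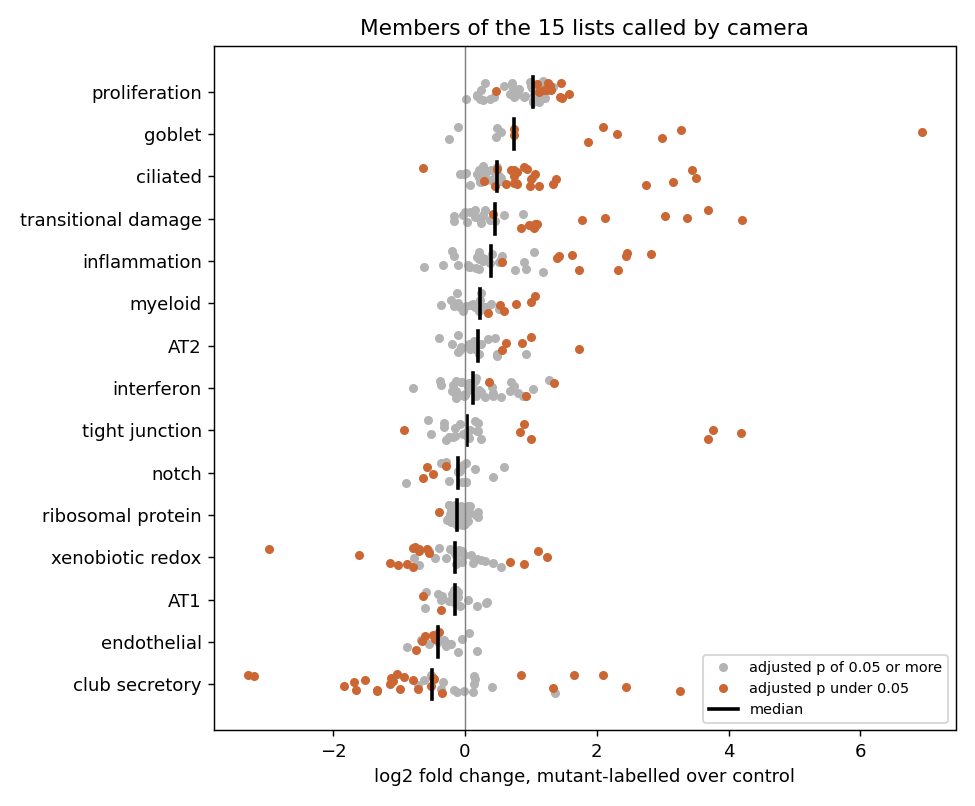
Log2 fold change, mutant-labelled over control, of each measured member of the 15 lists called by camera, ordered by list median (black bar), with members past the threshold in orange. The goblet list reaches from members near 0 to Dmbt1 at 6.93, and the club secretory list holds members on both sides of 0.

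The other 21 lists were not called by camera. Mesenchymal transition genes gave 4 higher and 1 lower of 27 (adjusted p 0.065, but 0.0102 without control 1, 0.0159 without control 4, 0.0451 without mutant-labelled library 2 and 0.0388 without mutant-labelled library 4), with Fn1 up 1.96-fold, Mmp14 1.74-fold, Pmepa1 1.59-fold and Cd44 1.31-fold and Zeb1 down 1.31-fold. Desmosome genes rose in 3 of 9 (Pkp3, Dsg2 and Dsc2; 0.0727), tuft cell and ionocyte genes in 3 of 10 (0.126) and neuroendocrine genes in 2 of 12 (0.318). Polarity genes gave 2 higher and 1 lower of 28 (0.841), matrix and integrin genes 1 higher of 30 (0.318), actomyosin genes 3 higher of 37 (0.402) and YAP targets 1 higher and 1 lower of 26 (0.66). Wnt genes gave 1 higher and 3 lower of 24 (0.493), with Wif1, Bambi and Apcdd1 lower. Death and p53 genes gave 2 higher and 1 lower of 36 (0.493), with Gdf15 up 3.67-fold. Fibroblast and muscle genes gave 1 higher and 2 lower of 21 (0.493), mesothelial genes 1 and 1 of 10 (0.291), and immediate early genes 1 and 1 of 29 (0.972). Hypoxia and glycolysis genes rose in 2 of 23 (0.931) and stress response genes of the endoplasmic reticulum in 1 of 26 (0.493). Basal cell (0.493), erythroid (0.79), lymphoid (0.931), antigen presentation (0.931) and mitochondrial genes (0.402) had 0 called members of 11, 7, 21, 23 and 13. Among these lists camera passed its threshold without control 1 for mesothelial genes (0.0127) and without control 4 for desmosome (0.0193) and matrix genes (0.0214). Without controls 2 and 3 it called lymphoid (0.00106), antigen presentation (0.0117), immediate early (0.0219), mitochondrial (0.0219) and erythroid genes (0.0422) lower and stress genes of the endoplasmic reticulum higher (0.0117). Without controls 1 and 4 it called mesenchymal transition (1.37e-05), matrix (0.000877), actomyosin (0.0189), desmosome (0.0214) and immediate early genes (0.0475) higher and mesothelial genes lower (0.0331). Without control 1 and mutant-labelled library 4 it called mesenchymal transition genes higher (0.0072) and mesothelial genes lower (0.00847). Mesenchymal transition genes also passed with the filter at 1 CPM (0.0423), with the replicate block (0.0392) and with no filter (0.0174), where tuft cell (0.0432) and desmosome genes (0.019) passed too. The small counts of called members moved with single libraries. Desmosome genes had 0 called without control 3 or mutant-labelled library 1, 2 or 3, 2 without control 2 and 1 without mutant-labelled library 4. Mesenchymal transition genes had 7 higher without control 1 or 4 and 2 without any other library. Without control 1, 6 YAP targets, 6 fibroblast and muscle, 5 Wnt, 4 matrix, 4 mesothelial and 3 polarity genes fell and 4 immediate early genes rose. Without control 4, 5 fibroblast and muscle and 4 matrix genes rose. Over single left-out libraries the lowest count of called genes was 0 for the polarity, Wnt, fibroblast, immediate early and hypoxia lists. Adjusted over the list alone, the counts became 3 higher for neuroendocrine, 4 for tuft cell and ionocyte and 3 for hypoxia genes, 2 higher and 2 lower for polarity, 2 and 4 for Wnt, 2 and 1 for immediate early and 2 and 3 for fibroblast genes, and were as before for the others. Median, mean and camera's direction differed in sign for the polarity, antigen presentation, hypoxia, lymphoid and immediate early lists, whose medians lay between -0.05 and 0.04.

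With the GC trend of each library removed, each of the 15 lists called by camera passed again, with adjusted p of at most 0.0212, and 0 of the other 21 did. Fewer members passed the gene test: 5 detoxification and redox genes fell instead of 12, 2 endothelial instead of 6, 1 Notch instead of 4, 0 alveolar type I instead of 2 and 0 ribosomal protein genes instead of 1. Likewise 6 proliferation genes rose instead of 13, 3 myeloid instead of 6 and 2 interferon instead of 3. The club list then gave 6 higher and 16 lower, and the ciliated, goblet, damage, inflammation and alveolar type II lists 18, 7, 12, 7 and 4 higher and 0 lower.

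Compared by their mean per library, 0 of 36 lists passed the exact permutation test after Benjamini-Hochberg adjustment. For 12 lists p was 0.0286, the smallest that 70 arrangements can give, with an adjusted value of 0.0858. Fry called 8 lists, with adjusted p from 0.000112 to 0.0253. The damage, goblet, ciliated, inflammation and tight junction lists were higher, and the club, endothelial and Notch lists lower.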

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

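Tests of a wrong label, of other cells as the source of Cdh1, of GC content, immune cells and glucocorticoid exposure in the controls and of a larger share of ciliated cells or a loss of club cell RNA were chosen after the result was seen. Tests on the controls replaced a first set that had compared controls 2 and 3 with controls 1 and 4. The test of a wrong label is the third version and that of a larger share of ciliated cells went back to its first: in each case the first had argued against the explanation and the second, run and seen, had left it open.

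In 14 of 316 groups of 4 libraries, 1 library stood far from the rest, where chance gives about 15.8. Control 1 stood apart in Gsta2 at 6.65 CPM, Bak1 at 29.82, Igfbp3 at 49.52, Cdh5 at 859.92 and mt-Nd2 at 1728.89. Il33 stood at 114.27 CPM in control 2, Cxcr6 at 6.64 in control 3 and Pkp3 at 28.54 in control 4. Mutant-labelled library 1 stood apart in Lfng at 56.07 CPM, Tes at 52.04 and Psat1 at 31.66. Mutant-labelled library 4 stood apart in Mmp14 at 113.34 CPM, Bambi at 28.3 and Rpl30 at 187.47.

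Cdh1 was not lower in the libraries labelled mutant. A wrong label of 1 library is argued against only as what hides a fall in the gene's sum. Cdh1 was called lower in none of the 8 fits without a library, and the lowest lower 95% bound of its ratio was 0.87. Its log2 fold change was -0.000229 without control 1 and -0.0202 without controls 1 and 4. These fits do not check the labels, since a sum cannot show the loss of floxed exons. Placed between the mean of the other group (0) and that of the rest of its own (1), on genes called without it, control 1 had a median of 0.45 and control 4 of 0.60, which alone settles neither label, although Scgb1a1 stood there at 14148 and 13469 CPM, against 3755.1 to 4418.7 CPM in mutant-labelled libraries. Counts from cells other than recombined club cells may hide a loss: the level of Sftpc, from alveolar cells that also express Cdh1, was 3.95 times that of Scgb1a1 in the mutant-labelled libraries and 1.33 times in controls, so most of the 3.95 follows from the fall of Scgb1a1 and the share of Cdh1 from other cells was not measured, although the series text describes a sort on GFP that would remove them from a GFP-positive fraction. Transcripts of the recombined allele that are still counted cannot be told apart from intact ones, since the table holds 1 sum per gene, whose ratio had a lower 95% bound of 0.902.

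The control libraries spread more widely than the mutant-labelled ones, with ranges of 49.6 and 7.1 on the first principal component. GC content was tested because its rank correlation with each library's deviation, across genes that are not independent replicates, was -0.01, -0.27, -0.22 and 0.23 in controls 1 to 4, but after the GC trend was removed the ranges were 47.7 and 8.1. A varying share of immune cells may contribute: the SD of 47 myeloid and lymphoid genes over the 4 controls averaged 0.50, above 100% of 10000 random lists matched on expression, and Ptprc stood at 111.3 ± 64 CPM in controls, although the series text describes removal of immune cells. Varying glucocorticoid exposure may contribute as well, since 10 induced genes, chosen to leave out 6 that had been seen to vary, reached the 99.87th percentile, and the 8 of them in no fixed or clock list the 99.61st. An SD ignores direction, however. Per1 stood at 293, 215, 223 and 305 CPM in controls 1 to 4, opposite to Klf9 at 247, 391, 387 and 239 CPM. Mt2 was highest in control 1, while most of the others followed Klf9. The random lists were drawn gene by gene, so a list whose members move together can rank high for other reasons. List means of proliferation and inflammation genes varied more over the controls (SD 0.567 and 0.497) than those of myeloid and lymphoid genes (0.391 and 0.388). Neither test tells whether immune cells or glucocorticoid exposure moved the other genes. Differences between animals, or a shared origin of mutant-labelled libraries 1 to 3, whose descriptions hold near numbers, stay open and untested. Controls 2 and 3 were the closest pair within a group, with a chi-square per gene of 4.88. Other pairs of controls gave 19.98 to 45.58. A shared origin of controls 2 and 3 was not tested either.

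A list of 10 regulators of multiciliogenesis was written after Mcidas, Ccno, Foxn4, Deup1 and Myb had been seen to rise. Its median log2 fold change was 1.88, against 0.45 for 42 other ciliated genes. Foxj1, Rfx2 and Rfx3 of the ciliated list were left out of both sets. Their log2 fold changes were 1.34, 0.54 and 0.21, all below the median of the 10, so the contrast depends on which genes count as regulators. A larger share of mature ciliated cells alone would give equal folds, if the 42 genes were expressed in those cells only. Over the 10 the medians differed by 1.43, beyond the quartile spread of 0.51. The mean difference per library ran from -2.81 to -2.44 in controls and from -1.14 to -0.92 in mutant-labelled libraries. Because the list was written after members had been seen to rise, this size is inflated. It shows unequal folds for these 10 genes and decides nothing for regulators in general. For the 4 regulators in no fixed list, Cdc20b (10.4-fold), Hes6 (1.92-fold), Trp73 (1.66-fold) and Gmnc (1.73-fold, not called), a larger share cannot be told apart, since their median lay 0.42 above, inside that spread. Loss of club cell RNA alone would move other cell types alike, although scaling would remove a rise that they share. It is argued against, since the ciliated list had a median of 0.48 and the endothelial list of -0.41. By camera with an estimated correlation neither list was called (adjusted p = 0.308 for each). A GC trend as the whole cause is argued against as well, since its removal left the difference over the 10 at 1.41. Cells newly entering the multiciliated programme may contribute, a hypothesis that counts of Mcidas-expressing cells in tissue would decide and these libraries cannot.

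Of the 35 distinct splits of the 8 libraries into groups of 4, the real one alone gave as many called genes (1 of 35), with 1325 calls against at most 1 in any other split. No smaller share can come from 35 splits. Mixed splits also count the group difference as spread, which keeps their calls low. A chance arrangement of labels is therefore unlikely at 1 in 35, and a shared origin of libraries within a group was not tested. For lists called by camera, 13 of 35 splits gave 15 or more, with up to 20 in another split, so chance cannot be excluded for the number of lists.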

How the results depend on the processing

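The alternatives without pairs of controls and with the GC trend removed were chosen after the data were seen. Counts of higher and lower genes, 924 and 401, stayed within 1.5 times under other scaling, other filters, limma-voom and a fit without robust estimation. They were 410 and 101 at an adjusted p under 0.01 and 406 and 96 at 2-fold or more. A surrogate variable gave 1407 and 785, limma-voom with quality weights 2794 and 2393, removal of the GC trend 565 and 124, and the fit without controls 1 and 4 gave 3750 and 3338. Lower genes alone moved to 886 with DESeq2, 625 without control 1 and mutant 4, and 223 without controls 2 and 3. The cause was not tested for these, except that stricter thresholds lower a count by construction. Leaving out 1 library gave 515 to 1517 higher and 146 to 1117 lower genes. Of the 1325 called genes, 695 were called with the same sign without controls 2 and 3, 1304 without controls 1 and 4 and 666 with the GC trend removed, and 0 reversed in any alternative. With the replicate number as a block the fit gave 865 and 371 genes and 16 lists. Same-numbered libraries did not deviate together, with correlations of 0.007, 0.129, -0.123 and 0.134, so the numbers were not treated as pairs. The Cdh1 log2 fold change ranged from -0.000229 to 0.129 over left-out libraries and was -0.0202 without controls 1 and 4, and it never passed the threshold. Camera called 13 to 16 lists when a library was left out, 1 with an estimated correlation and 8 with fry. Of 107 called named genes, 36 lost the call with the GC trend removed, 32 without controls 2 and 3 and 34 without mutant-labelled library 1. Small uncalled values changed sign: Slc4a1 to 0.0521 and Hbb-bt to 9.14e-05 with quality weights, Evpl to -0.0339 and Hba-a2 to -0.128 without controls 2 and 3, and Cd8a to 0.058, Slc4a1 to 0.188 and Hbb-bt to 0.0631 without controls 1 and 4. Hbb-bt ranged from -0.222 to 0.0506 over left-out libraries. No fit with sex was run. With 4 libraries a group, changes of 1.5-fold were recovered in 53.7% of simulated genes, which left out the least expressed.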

Other observations

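The lists in this part were written after the data were seen. Cardiac muscle genes, which in the mouse are also expressed around pulmonary veins, were lower in 14 of 20 measured members and higher in 0. Endothelial genes, with a median log2 fold change of -0.41, and Pecam1 (1.39-fold) were lower in the same libraries, and Epcam was 1.53-fold higher. Actc1 fell from 177.6 ± 36.9 to 79.0 ± 15.3 CPM, Ckm fell 3.10-fold, Casq2 2.33-fold and Csrp3 2.28-fold, while Myh6, at 375.9 ± 183 and 196.5 ± 51.7 CPM, was not called. Camera gave this list an adjusted p of 8.28e-20, and an adjusted p of 0.0547 with an estimated correlation. Over the 5 lists written before the last one was added, camera gave an adjusted p of 0.0456 with an estimated correlation, so the added list ended that call.

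Genes of the response to interleukin 4 and 13 rose in 5 of 20. Retnla rose from 214.9 ± 27.5 to 2053 ± 548 CPM, Chil3 2.01-fold, Ccl8 5.14-fold, Mrc1 1.72-fold and Il13ra1 1.19-fold, while the goblet cell gene Clca1 stood at 127.0 ± 128 and 178.4 ± 107 CPM. The list mean was 4.59, 4.28, 4.42 and 4.25 log2 CPM in controls 1 to 4 and 5.33, 5.17, 4.76 and 4.43 in mutant-labelled libraries 1 to 4, so the groups overlapped. Chil3 and Mrc1 are also members of the myeloid list, of which Cd14 (2.10-fold) and Cd68 (1.51-fold) rose in the same libraries, and Epcam was 1.53-fold higher. Camera gave an adjusted p of 8.52e-07, and an adjusted p of 0.103 with an estimated correlation. Of 16 clock genes, Npas2 rose 2.90-fold, Nfil3 rose 2.31-fold and Tef fell 1.57-fold, with an adjusted p of 0.284 by camera. Glucocorticoid-induced genes had 0 called members of 16, with an adjusted p of 0.113 by camera.

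Itln1 stood at 1.90, 166.0, 1.06 and 1.54 CPM in mutant-labelled libraries 1 to 4 and at 28.9, 45.3, 101.0 and 26.1 CPM in controls 1 to 4.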
